A study of Arabidopsis thaliana with 6 samples.

How the data were processed

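Total RNA of whole seedlings was labelled with biotin and hybridised to Affymetrix Arabidopsis arrays, 3 of empty-vector control plants and 3 of 35S-PaWRKY1 plants, per the labels' protocols. The labels call the samples of each group biological replicates; whether these came from separate transgenic lines or sowings is not stated, so p-values measure the spread between these samples. The array total was 6, and all 6 were used.

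The deposited values are on a log scale, read here as log2 values; the submitters' processing notes name MAS5 and RMA, with no version and no role for either. Tested on the file, each probe set is centred on the mean of the 3 control arrays, the largest absolute control mean being 1.3e-06. The expression level, the log base, the direction and the normalization between arrays are not given in the sources used here. Base 2 is the convention of RMA, and a fold is printed only as "if log2". The column medians were -0.02428, 0.007748 and 0.01369 for control replicates 1 to 3 and -0.02916, -0.03502 and -0.04642 for 35S-PaWRKY1 replicates 1 to 3. They differed by at most 0.0601, under the limit of 0.2 set for normalizing again, so the values were used as deposited.

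Of 22810 probe sets, 64 Affymetrix control probe sets were left out and 22746 were tested. Genes were named from GEO's platform annotation, which can be old: 13513 probe sets had 1 gene, 503 had several and 8730 had none given. No gene was named from a probe set with several genes. Symbols were updated through RefSeq's table of assembly TAIR10.1; 29 entries had no match there. For gene lists, single-gene probe sets of a gene were averaged, giving 13355 genes, of which 147 had more than 1 probe set.

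Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probe sets (or all genes for list members) and a threshold of 0.05. SE values are those of the moderated fit. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The 40 lists covered defence, hormones, stress, nutrition, metabolism, development, tissue markers, the clock and reference genes; 4 were tested, 31 were described only and 5 had no member matched to a probe set. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

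The numbers of the labels were checked for pairing. The deviations of same-numbered arrays from their group means correlated across probe sets by 0.314, 0.194 and 0.453 for replicates 1, 2 and 3. All are over 0.1, so the numbers were taken to pair the samples, from the data and not from a statement in the labels. Control replicate 1 and 35S-PaWRKY1 replicate 2, of unlike number, correlated by 0.171. Deviations cancel out within a group, so a match of replicate 3 alone raises the correlations among replicates 1 and 2. The pairing of replicates 1 and 2 is therefore assumed and not shown. The fit without a block stayed the main one, as chosen before the data were examined, and the value with the block is given where it changes a call.

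Genes were named by a rule fixed before the data were examined: past the threshold, up to 12 each way with non-overlapping groups; where fewer than 5 passed in a direction, the 6 with the smallest p among the 1579 single-gene probe sets with a name beyond the locus tag, described as not passing; up to 4 members of each list; and always PR1, PR2, PR5 and PDF1.2. The rule's limit to probe sets above the median level, the filter on dim probe sets and the choice of the brightest probe set per gene need a level and were not applied. The rule allowed 82 list members. For their genotype difference the text names 41: those of the 4 tested lists, PDF1.2, those at an unadjusted p under 0.1 and those called over the list alone with the block. That narrowing was made after the values were seen. STZ, 1 of the other 41, is named among the observations for its spread between controls. STZ, COR15B, ATHSP22.0, CRT1b, ATERDJ3B, AT3G12900, WRKY6 and AT1G04770, also of the other 41, are given beside higher genes for comparison only. Of these 41, 22 changed sign under some alternative, 43 changes in all, and 0 crossed the threshold over all genes.

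Alternatives were a normalization to equal quantiles, median centring, array weights, the replicate number as a block, each array left out in turn, an absolute difference of at least 1, an adjusted p under 0.01, an equal-variance test, an estimated correlation and fry. Chosen after seeing the data were robust eBayes, leaving out both replicate 3 arrays, the block as a random effect, gene families by symbol stem, the random gene sets set against them, the test of mitochondrion-encoded genes, the look at spike-ins, the simulation of equal quantiles, and the adjustment over the list alone repeated with each array left out. The result of 1 family is not reported here. The fits were tested on simulated data with known differences. Among 22746 simulated probe sets, 8 calls were false, and camera gave a p under 0.05 for 5 of 50 unshifted lists of 6 genes with the preset and 1 with the estimated correlation.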

Results

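Transcript levels were measured in whole Arabidopsis seedlings, shoot and root together, 7 days old and grown on full-strength MS medium after 2 days of seed vernalization. The study held 6 Affymetrix arrays. Empty-vector controls gave 3 arrays, and plants carrying PaWRKY1 behind the cauliflower mosaic virus 35S promoter, which drives strong expression in most tissues, gave the other 3. PaWRKY1 is named as a member of the WRKY family, plant transcription factors many of which act in defence and senescence. The values are centred on the mean of the control arrays for each probe set, so they give differences between arrays and not expression levels. They were read as log2 values by the convention of the summary method, and a fold is given only as what the difference would be if that base is right. The direction, higher value for more transcript, is also taken by convention. The transgene itself was not analysed here.

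The arrays did not separate cleanly by genotype over all probe sets. The root mean square difference between 2 arrays averaged 0.325 within a group (range 0.2559 to 0.4063 over 6 pairs) and 0.343 between groups (range 0.2799 to 0.4397 over 9 pairs). The ratio of the averages was 1.06. The average between groups includes the same-numbered pairs, at 0.2942, 0.2799 and 0.3492 for replicates 1, 2 and 3. All pairs within a group differ in number, so an effect shared by number can lower this ratio. Pearson correlations across probe sets between arrays of different groups ran from -0.391 to 0.303, and centring on the controls forces the control arrays to correlate negatively among themselves. The first principal component, with 41.7% of the variance, set both replicate 3 arrays apart, at 40.73 for the control and 12.84 for 35S-PaWRKY1, against -22.42 to -2.734 for the other 4 arrays. The second component, with 23.83% of the variance, held all 3 controls at 8.432 or above and the 35S-PaWRKY1 arrays at 1.049 or below.

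**Figure D1:**
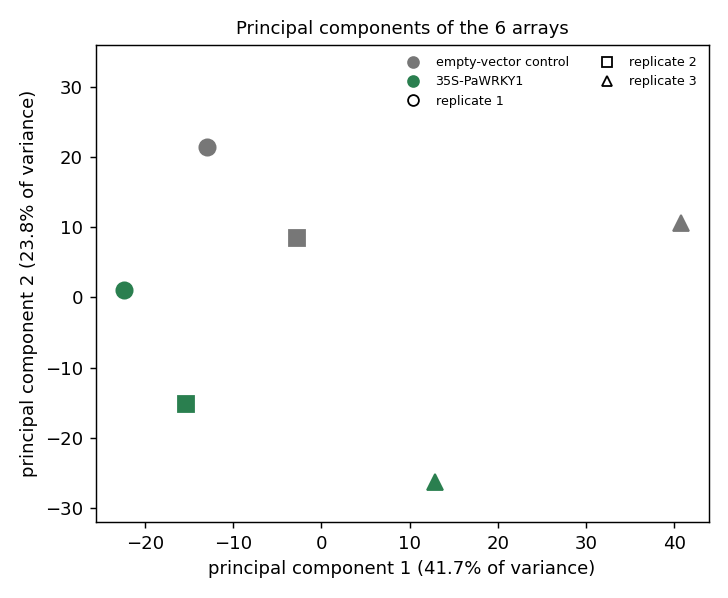
Principal components 1 and 2 of the 6 arrays over all tested probe sets, with the group as colour and the replicate number as symbol. The replicate 3 arrays lie at 40.73 (control) and 12.84 (35S-PaWRKY1) on component 1, and the other 4 arrays lie below 0.

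The comparison of 35S-PaWRKY1 with the empty-vector control asks which transcripts differ when PaWRKY1 is expressed from this promoter. Few transcripts passed the test: 6 probe sets rose and 1 fell among 22746. The named gene among them was ECS1 (AT1G31580), known as a pathogen-inducible gene, which rose by 1.08 log2 units (SE 0.0973, n = 3 per group; 2.11-fold if log2). The probe set with the largest rise, 245532_at, was 2.37 log2 units above control (SE 0.112, n = 3 per group; 5.17-fold if log2). It is unnamed here, not without a gene. Every 35S-PaWRKY1 array lay outside the range of the control arrays for each of the 7.

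With limma over all probe sets, 245532_at had an adjusted p of 0.00367, and the other 6 shared an adjusted p of 0.0481. The 5 other unnamed probe sets were 249410_at, which rose by 1.37 (SE 0.12), 261570_at by 1.28 (SE 0.119), 258566_at by 1.17 (SE 0.109) and 259773_at by 1.15 (SE 0.0995), and 249964_at, which fell by 1.21 (SE 0.0953). With the replicate number as a block, 245532_at, 249410_at and 261570_at stayed past the threshold, at adjusted p of 0.0313, 0.041 and 0.041. The block took ECS1 to 0.0679, 249964_at to 0.0679, 259773_at to 0.073 and 258566_at to 0.0633. It brought in AT2G25510 (1.52 above control, adjusted p 0.082 without and 0.0342 with the block), AT3G05640 (1.57, 0.424 and 0.049) and the unnamed 248337_at (1.59, 0.507 and 0.0342). Leaving out 35S-PaWRKY1 replicate 2 left 0 calls in limma, and leaving out each other array left 1, which was 245532_at.

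**Figure D2:**
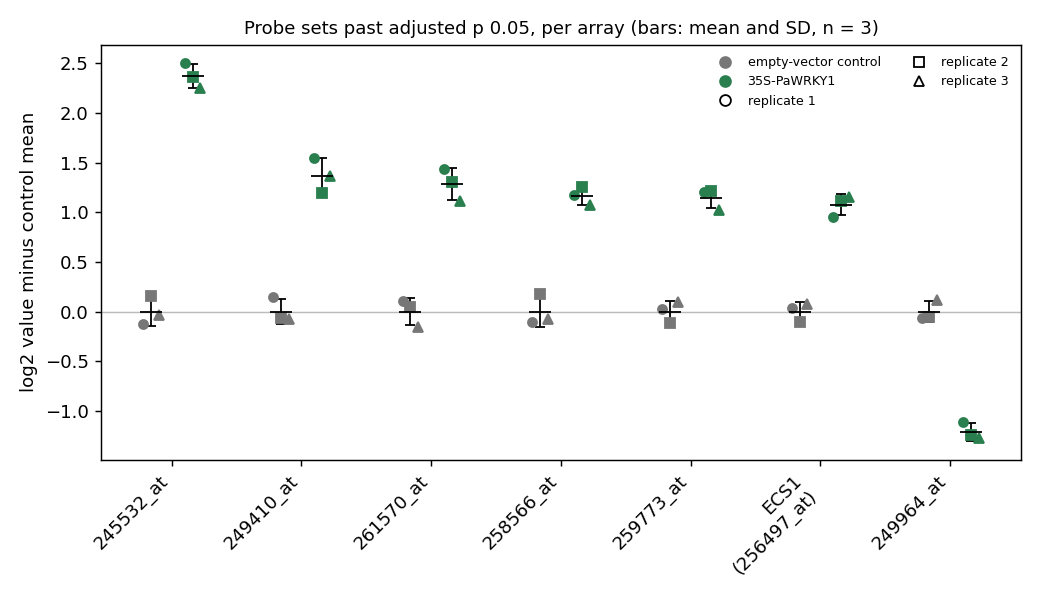
Values of the 7 probe sets past an adjusted p of 0.05, on the vertical axis as log2 value minus the control mean. Points are single arrays with the replicate number as symbol, and bars are the mean and SD of 3 arrays. The 35S-PaWRKY1 arrays lie outside the control arrays for each, by a mean of 2.37 for 245532_at and 1.08 for ECS1.

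Beyond these, 1821 probe sets had an unadjusted p under 0.05 in limma, 901 higher and 920 lower, where 1137 were expected by chance of independent arrays. Without 35S-PaWRKY1 replicate 2 the count was 1062, below that value. Leaving out each other single array gave 1643 to 1936, so the lower number of arrays alone does not account for 1062. If same-numbered arrays are paired, the count expected by chance is not 1137, so 1062 does not settle whether the excess was lost. The count was 1643 to 2704 under the other settings, apart from 1022 after a normalization to equal quantiles, which the centring on the controls makes a poor test. The groups did not overlap for 3300 probe sets, or 14.5%, where chance gives 10% for independent arrays.

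Other named genes with the smallest p did not pass. Among those above control were the chaperone gene Hsp70-2 (0.82, SE 0.11, adjusted p 0.17) and SGT1A (1.1, SE 0.18, adjusted p 0.248), a co-chaperone of plant immune receptors. The cytochrome P450 genes CYP71B26 (1.15, SE 0.179) and CYP71B29 (0.56, SE 0.0878) and the thionin gene THI2.2 (0.73, SE 0.116), for a small antimicrobial peptide, each had an adjusted p of 0.225. Below control were the cyclophilin gene CYP59 (-0.45, SE 0.0812, adjusted p 0.3), the serine carboxypeptidase-like gene SCPL34 (-0.72, SE 0.134, 0.332) and RR16 (-1.15, SE 0.228, 0.351), a cytokinin-inducible response regulator. TBL45, of a family of cell wall acetylation genes, was at -0.80 (SE 0.16, adjusted p 0.351), WLIM1, for an actin-binding LIM protein, at -0.38 (SE 0.084, 0.379), and NDP1 at -0.36 (SE 0.0793, 0.382).

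Few defence genes of the fixed lists could be matched to a probe set through the gene table used here: 2 of 23 for salicylic acid, 4 of 30 for jasmonate and 3 of 20 for pattern-triggered immunity, too few to test as sets. The others are not shown to be missing from the array, since 8730 probe sets have no gene given, and "measured" here means matched. PR1, PR2 and PR5, marker genes of salicylic acid defence, had no probe set with that gene name here and were not analysed. PDF1.2, a defensin gene induced by jasmonate and ethylene, was 0.40 above control (SE 0.167, n = 3 per group), with an adjusted p of 0.643 over all genes and 0.137 adjusted over the list alone in limma. With the block, the second became 0.0395. The related PDF1.2b was at 0.37 (SE 0.175) and THI2.1 at -0.27 (SE 0.145), whose value adjusted over the list alone went from 0.137 to 0.0395 with the block. GRX480, a glutaredoxin gene induced by salicylic acid, was 0.34 above control (SE 0.116), with an adjusted p of 0.55 over all genes and 0.042 adjusted over the list alone. Among the 6 WRKY genes measured, 0 passed over all genes, 0 passed adjusted over the list alone and 0 had an unadjusted p under 0.05 in limma. The values were 0.66 for WRKY22 (SE 0.374), -0.44 for WRKY53 (SE 0.686), -0.17 for WRKY42 (SE 0.0863) and -0.13 for WRKY20 (SE 0.117). In the list of pattern-triggered immunity, the value of WRKY22 adjusted over the list alone went from 0.259 to 0.0268 with the block. Without 35S-PaWRKY1 replicate 1 the difference of WRKY22 was 0.218, and without 35S-PaWRKY1 replicate 3 that of THI2.1 was -0.145. The control SD of WRKY53 was 1.36, and its difference was 0.35 above control when control replicate 1 was left out.

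Of the 40 gene lists fixed before the data were examined, 35 had a measured member, with 89 different genes. Over all genes, 0 of the 89 passed in limma, and 21 had an unadjusted p under 0.05. Over all probe sets, 1821 of 22746 had such a p. The listed genes were chosen by function, so setting these counts side by side is not a test. Adjusted over the list alone, 16 genes in 12 lists passed, 12 of them above and 4 below control. That adjustment does not correct for the testing of 35 lists, so some of these calls can be due to chance. For 3 of the 16 (GI, UGT74B1 and AT3G10040), each alone in its list, this is the unadjusted p. These 12 lists held 1 to 4 measured genes, so their members are described singly. With each array left out in turn, 6 of the 16 kept their call over the list alone: GI, BGLU28, UGT74B1, BCAT4, AT2G31790 and RR16. The other 10 lost it with at least 1 array left out.

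The clock gene GI, which promotes flowering in long days, was 1.31 above control (SE 0.23, adjusted p 0.383 over all genes). Its p over the list alone, 0.000773, is unadjusted, since it was the single measured gene of 26 in the clock list. COR15A, a cold-regulated gene for a chloroplast-protecting protein, was 1.74 above control (SE 0.434), at 0.45 and 0.0211. The dehydrin gene COR47 was at 0.59 (SE 0.27), and its value adjusted over the list alone was 0.134 without and 0.00982 with the block. Without 35S-PaWRKY1 replicate 1 the difference of COR47 was 0.337. The same cold list also held COR15B at 0.14 (SE 0.189) and STZ at -0.98 (SE 0.819). SAG29, a sugar transporter gene of senescing leaves, was at 0.91 (SE 0.224, 0.015 adjusted over the list alone). The same senescence list also held WRKY6 at 0.07 (SE 0.132) and WRKY53 at -0.44 (SE 0.686). The iron deficiency regulators BHLH101 and PYE were at 0.87 (SE 0.208, 0.0125) and 0.66 (SE 0.235, 0.039). The other measured gene of the iron list, AT3G12900, was at -0.08 (SE 0.252). BGLU28, a beta-glucosidase gene induced by sulfur deficiency, was at 0.93 (SE 0.215, 0.00723), and the other measured gene of its list, AT1G04770, at 0.17 (SE 0.19). The highest values adjusted over the list alone with 1 array left out were 0.084 for COR15A, 0.0653 for SAG29, 0.0571 for BHLH101, 0.129 for PYE, 0.138 for GRX480, 0.122 for AT3G10040, 0.101 for ARR15, 0.17 for XTH26 and 0.0559 for HCT and CCR2.

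In secondary metabolism, 3 glucosinolate genes lay above control and passed over their lists alone. Few genes were matched: 1 of 15 for camalexin and indolic glucosinolates and 2 of 15 for aliphatic glucosinolates. The glucosyltransferase gene UGT74B1 was at 0.79 (SE 0.169, 0.00235, unadjusted since it was the single measured gene of its list), BCAT4, which starts methionine chain elongation, at 0.56 (SE 0.159, 0.00985) and the glucosyltransferase gene AT2G31790 at 0.49 (SE 0.133, 0.00985). On phenylpropanoids and lignin, 2 of 18 genes were matched, HCT and CCR2. Both were above control, at 0.50 (SE 0.155) and 0.69 (SE 0.221), each with 0.0169 adjusted over the list alone. These genes had adjusted p of 0.45 to 0.535 over all genes.

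The type-A response regulators ARR15 and RR16, negative regulators of cytokinin signalling that cytokinin induces, were both below control, at -1.16 (SE 0.454) and -1.15 (SE 0.226 at gene level). Their p adjusted over the list alone was 0.0381 and 0.00294. Also below were AT3G10040, the single measured gene of the hypoxia list, at -0.41 (SE 0.163, unadjusted p 0.0402), and XTH26, a root hair cell wall gene, at -0.39 (SE 0.124, 0.0496), which the block took to 0.0632. The difference of ARR15 was -0.6 without control replicate 3, and that of AT3G10040 was -0.251 without control replicate 1.

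**Figure D3:**
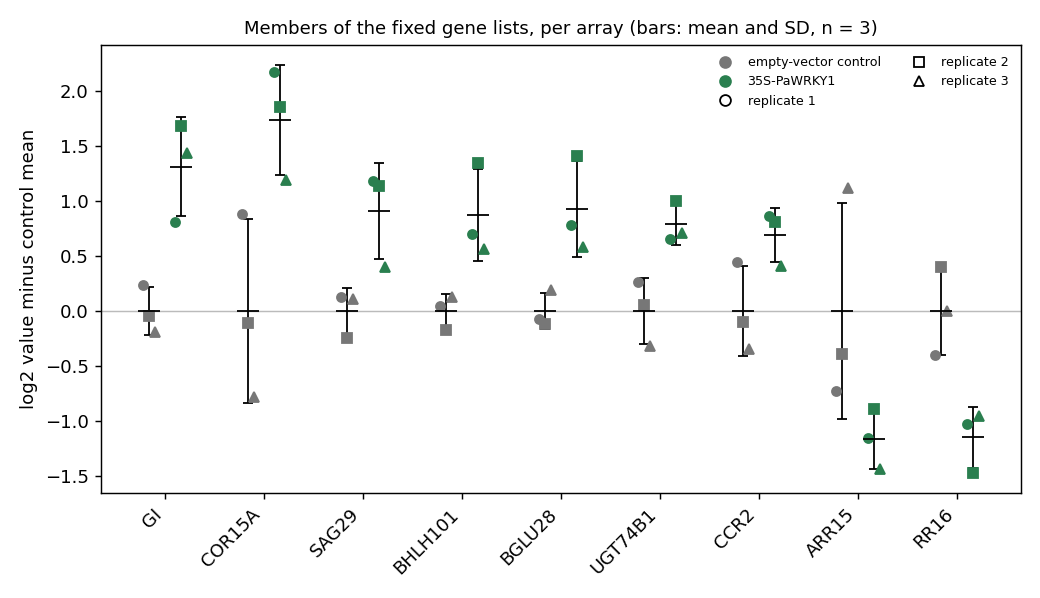
Values of 9 members of the fixed lists, on the vertical axis as log2 value minus the control mean. Points are single arrays with the replicate number as symbol, and bars are the mean and SD of 3 arrays. GI, at a mean of 1.31, and COR15A, at 1.74, lie above control, and ARR15 and RR16 lie below it, at -1.16 and -1.15; none of these passed over all genes.

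The other lists had 0 calls in limma over all genes and 0 adjusted over the list alone without the block. In the heat shock list, AT5G37670 was at 1.04 (SE 0.366) and AT1G53540 at 0.40 (SE 0.192), with 0.0762 and 0.116 adjusted over the list alone, and 0.0392 and 0.0212 with the block. The first was at 0.677 without control replicate 3 and the second at 0.251 without control replicate 1. GID1B, a gibberellin receptor gene, was at 0.42 (SE 0.139, 0.0579), and MCCB, of branched-chain amino acid breakdown, was at -0.28 (SE 0.12, 0.149). PORB, of chlorophyll synthesis, was at -0.36 (SE 0.231), with 0.218 adjusted over the list alone and 0.0288 with the block, and was at -0.173 without control replicate 3. The 4 measured reference genes had a median of -0.135, and the median over all probe sets was -0.0366.

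Tested as sets with limma's camera, 0 of 4 lists shifted relative to the other genes. Only parts of the lists were tested: 7 of 24 auxin, 5 of 19 flavonoid and anthocyanin and 6 of 35 photosynthesis genes were matched. The WRKY family was the 6 genes matched by symbol, so members without a match were not tested. The auxin list had 5 of 7 genes above control and a median of 0.22, with an adjusted p of 0.11. GH3.3, an auxin-conjugating enzyme gene, was at 0.33 (SE 0.161), HAT2 at 0.45 (SE 0.28), IAA29 at 0.30 (SE 0.194; 0.0681 without 35S-PaWRKY1 replicate 1) and LBD29 at -0.17 (SE 0.0988). With single arrays left out GH3.3 ran down to 0.155, HAT2 from 0.246 to 0.773 and LBD29 up to -0.1. Flavonoid and anthocyanin genes had 3 of 5 above control and a median of 0.09, with an adjusted p of 0.11. Of these, UGT78D1 was at 0.53 (SE 0.202) and AT4G14090 at 0.20 (SE 0.125; 0.0821 without 35S-PaWRKY1 replicate 2). DFR was at 0.09 (SE 0.185) and UGT78D2 at -0.16 (SE 0.348), and both changed sign when 1 array was left out. Nuclear photosynthesis genes had 5 of 6 above control and a median of 0.06, with an adjusted p of 0.166; LHCB4.1 was at 0.09 (SE 0.0949), PSAE-1 at 0.08 (SE 0.0729), PRK at 0.06 (SE 0.084) and SBPASE at -0.07 (SE 0.0911). With single arrays left out LHCB4.1 ran from 0.0301 to 0.169, PRK from 0.035 to 0.116 and SBPASE from -0.122 to -0.0188, and WRKY20 from -0.235 to -0.0547. The WRKY family had a median of -0.08, a mean of -0.004 and an adjusted p of 0.956, with camera's direction up. With an estimated correlation the adjusted p was 0.393 for the first 3 lists and 0.963 for the WRKY family, so no call was made with either correlation.

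On simulated data with the same number of arrays and probe sets, the limma test recovered 10% of differences of 0.5 log2 units, 76% of those of 1 and 96% of those of 2. That simulation gave 144 calls, against 7 in the data, which eases the adjusted threshold. Its noise was independent between arrays, with no effect shared by replicate number. The shares can therefore overstate what could be detected here. The number of arrays, 3 per group, limits the precision of every value above.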

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

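Robust eBayes, the random block and leaving out both replicate 3 arrays were chosen after seeing the data. The count of 7 probe sets stayed at 7 with median centring and with a difference of at least 1, and was 6 with the replicate number as a block (6 higher, 0 lower, 3 shared with the 7) and 10 with the block as a random effect. Array weights gave 11. The count was 0 after normalizing to equal quantiles, 0 without both replicate 3 arrays, 0 with an equal-variance test, 1 with robust eBayes and 1 at an adjusted p under 0.01. Leaving out single arrays gave 0 to 1. At an unadjusted p under 0.05 the settings with 0 calls had 1022 (quantile), 1914 (both replicate 3 arrays out), 1745 (equal-variance) and 1062 (without 35S-PaWRKY1 replicate 2). Equal quantiles are a poor test of the count, since centring narrows the control arrays (SD 0.1649 to 0.2393, against 0.2753 to 0.2864). On simulated values centred alike, that step took 144 calls to 109 and 1313 unadjusted p under 0.05 to 706. Most calls were kept there and 0 here, but 144 calls ease the adjusted threshold, so the shares kept cannot be compared. In the data, the count of unadjusted p under 0.05 fell as well, from 1821 to 1022. The simulation therefore does not decide whether that step alone accounts for the loss of all 7. Leaving out arrays lowers the number of samples; the cause of the other moves was not tested. The adjusted p of 245532_at ran from 0.0252 to 0.0799 over the left-out arrays, and that of ECS1 from 0.135 to 0.442.

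The count of shifted lists, 0, became 2 with array weights (auxin and flavonoids, each at an adjusted p of 0.0366), 1 without both replicate 3 arrays (auxin) and 0 to 1 with single arrays left out: flavonoids without 35S-PaWRKY1 replicate 1 and auxin without 35S-PaWRKY1 replicate 3. The block left it at 0, as did fry. The cause was not tested. With single arrays left out the auxin mean, 0.162, ran from 0.0582 (without 35S-PaWRKY1 replicate 1) to 0.276 (without 35S-PaWRKY1 replicate 3). The flavonoid mean, 0.13, ran from 0.018 (without 35S-PaWRKY1 replicate 2) to 0.269 (without 35S-PaWRKY1 replicate 1). The WRKY family mean turned from -0.004 to 0.032 with median centring, 0.0467 with array weights, 0.0028 without both replicate 3 arrays, and ran from -0.12 to 0.143 with single arrays left out. Over the left-out arrays DFR ran from -0.0799 to 0.231, UGT78D2 from -0.447 to 0.234 and WRKY53 from -0.868 to 0.35. STZ ran from -1.64 to 0.0495 and JRG21 from -0.883 to 1.36, with JRG21 at -0.762 under array weights and -0.652 without both replicate 3 arrays. None of the other genes named for a genotype difference turned under these alternatives. Of the 16 genes called over their list alone, 10 lost that call with at least 1 array left out: every array except control replicate 1 ended the call of XTH26, and every one except 35S-PaWRKY1 replicate 1 that of PYE. Control replicate 2 ended those of GRX480, COR15A, SAG29, HCT, CCR2, BHLH101 and AT3G10040, and 35S-PaWRKY1 replicate 2 all of these but BHLH101, and ARR15. 35S-PaWRKY1 replicate 1 ended those of GRX480, COR15A, SAG29, HCT, CCR2 and ARR15, and replicate 3 those of AT3G10040 and ARR15. Control replicate 1 also ended that of AT3G10040 and control replicate 3 that of GRX480. The reference gene median stayed between -0.157 and -0.0719, and the ratio of distances between 0.986 and 1.11.

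The filter on dim probe sets, the eBayes trend and the brightest probe set per gene were not run, since the level is not in the values used here; a larger pseudocount was not run because the values are logs. Signal over background is not known, so dim probe sets could not be told from bright ones. The block changed no call other than those given with the results.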

Other observations

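The comparisons and tests on replicate 3 (except that of 3' over 5' signal), the families, the CYP71B genes, the wider heat set and the splits without a block were chosen only after the result was seen. Plastid-encoded transcripts differed between replicate numbers in both genotypes. Fitted with the genotype as a term, replicate 3 against replicates 1 and 2 gave 324 probe sets past an adjusted p of 0.05 in limma, 248 higher and 76 lower. Of 69 plastid-encoded genes, 46 rose and 2 fell in replicate 3, with a median of 1.32 log2 units. Both replicate 3 arrays showed it: ndhH, of the plastid NDH complex, was 3.68 higher in the control and 3.78 in 35S-PaWRKY1, rpoB, a plastid RNA polymerase subunit, 3.07 and 3.12, and accD, of fatty acid synthesis, 2.89 and 2.80. The photosystem gene psaA was 3.24 and 2.92 higher. The rise was uneven, since rbcL rose by 2.69 (SE 0.254) and psbA by 0.93 (SE 0.0974), while petD fell by 2.44 (SE 0.141) and psbN by 0.95 (SE 0.131). The 6 nuclear photosynthesis genes had a median of -0.017. Between genotypes, 0 of the 69 passed in limma, 2 had an unadjusted p under 0.05, and the set had a camera adjusted p of 0.265, 0.0253 with the block and 0.865 with an estimated correlation. Outside the plastid, the late embryogenesis abundant gene LEA4-5 fell by 1.80 in replicate 3 (SE 0.225, adjusted p 0.0236).

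Within the CYP71B subfamily of cytochrome P450 genes, singled out after the values were seen, 4 of 19 measured members had an unadjusted p under 0.05 and 0 passed over all genes in limma. They were CYP71B26 at 1.15 (SE 0.178), CYP71B23 at 0.57 (SE 0.192), CYP71B29 at 0.56 (SE 0.0851) and CYP71B28 at 0.48 (SE 0.193). Over 13 alternatives CYP71B23 ran from 0.384 to 0.777 and CYP71B28 from 0.298 to 0.649. The other 15 lay between -0.175 and 0.346. With fry's mixed test, 5 of 31 families passed, the serine carboxypeptidase-like (SCPL, adjusted p 0.00179), beta-glucosidase (BGLU, 0.00241), SWEET sugar transporter (0.0275), cytochrome P450 (0.0289) and tetraspanin (TET, 0.0289) families, and 0 passed with camera. SWEET1 was at 0.67 (SE 0.138), SWEET17 at 0.53 (SE 0.144) and SWEET11 at -0.41 (SE 0.105). That test does not compare a family with other genes, and 19% of 200 random sets of 20 genes had a mixed p under 0.05. Of 1000 random sets of the same size, drawn after the families had passed and not adjusted for the 31 families, 10 had a mixed p as low as the BGLU family, 13 as low as SCPL, 61 as low as SWEET, 75 as low as TET and 76 as low as the cytochrome P450 family.

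Why the replicate 3 arrays stand apart was weighed with 4 tests. A batch or day shared by same-numbered samples predicts that their deviations correlate, and the lowest correlation was 0.194, seen before that test was written. Control replicate 1 and 35S-PaWRKY1 replicate 2, of unlike number, reached 0.171, so the test does not decide this for replicates 1 and 2. RNA degradation or incomplete labelling predicts a larger excess of 3' over 5' signal in both replicate 3 arrays. The lower of them was at -0.15, under the highest of the other arrays at 0.0963, which argues against a loss toward the 5' end. That ratio does not test the yield of labelling or hybridization. All 18 hybridization spike-in probe sets were lower in replicate 3 than in replicates 1 and 2 in both groups, with medians of -0.472 in the control and -0.563 in 35S-PaWRKY1. So were 19 of 27 for the poly(A) spike-ins, with medians of -0.0747 and -0.229. Several probe sets share each spike-in transcript, so they are not separate observations. The transcripts are bioB, bioC, bioD and cre for hybridization, and dap, lys, phe, thr and trpn for poly(A). A technical difference of the replicate 3 arrays in spike-in amount, labelling or hybridization therefore stays open. More plastids or green tissue predicts a general gain of plastid RNA, and the 2 plastid genes that fell argue against that as the whole cause. A gain of all organelle RNA without poly(A) tails alike, through its priming, predicts that mitochondrial transcripts rise as well. The 11 mitochondrion-encoded genes measured had a median of 0.0154 in replicate 3 (SD 0.362, range -0.832 to 0.407), against 1.32 for the plastid genes, and nad5 fell. This and the fall of petD and psbN argue against such a gain as the whole cause, although the level of these probe sets is not known. The probe set for 25S ribosomal RNA, also without such tails, was at 1.67 in control replicate 3 and -0.992 in 35S-PaWRKY1 replicate 3. Priming that differed between plastid transcripts stays open, untested, as does a difference in growth between batches.

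Noticed for their small p were 5 genes named for heat stress or chaperones, with 0 past the threshold over all genes. These were Hop3 at 1.77 (SE 0.415), Hsp70-2 at 0.82, HSA32 at 0.45, Hop2 at 0.42 and BOB1 at 0.37. In the fixed heat shock list, AT5G37670 and AT1G53540 were at 1.04 and 0.40, but ATHSP22.0 was at -0.11. CRT1b and ATERDJ3B of the unfolded protein response list, in neither set tested below, were at 0.04 and 0.02. A shared shift of heat genes was the hypothesis. The first test used the remaining heat-named genes, which proved to be Hop1 alone, at -0.111. By its rule as written beforehand this counted against the hypothesis, but 1 gene is too few and the outcome was set aside as undecided, a minimum of 3 genes being added afterwards. A wider set that added the fixed heat shock list had 4 genes besides the 5 and a median of 0.144, with a camera p of 0.2 and 0.33 with an estimated correlation. Neither test decides it. Whether 1 pair of arrays carried the 5 genes also stays open. The ratio of the smallest to the largest pair median was 0.786, but genes picked for small p favour even pairs, so it decides nothing. The rule written beforehand counted this ratio against 1 pair carrying them; it was set aside after the value was seen.

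A stretch of chromosome that differs between the lines, such as one near an insertion, was tested on gene order of TAIR10.1. The test covers 13264 genes with a single-gene probe set and a place in that order. The 8730 probe sets with no gene name here, 6 of the 7 called among them, could not enter it. Among the 100 of these genes with the smallest p, 3 pairs lay within 5 genes of each other, against a median of 1 and a 95th percentile of 4 in 10000 random draws, so no excess was detected among them.

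The 6 arrays split 10 ways into 3 and 3. The real split was the 1 with as many as 7 probe sets called, and the highest other gave 0. Of the 4 splits that part all 3 pairs, fitted with the block, the real one was the 1 with as many as 6 calls, and the highest other gave 0. For lists, all 10 splits had as many as the real 0, and the highest other had 1. These splits are too few for a share under 0.05. At an unadjusted p under 0.05, the real split gave 1821 probe sets, and the other 3 that part all pairs gave 416, 522 and 786. The 6 splits that part 1 pair gave 372 to 2381, and the one at 2381, above the real split, had both replicate 3 arrays and control replicate 2 on one side.

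Some transcripts varied more between control arrays than between genotypes. STZ, a zinc finger gene of rapid stress responses, was at 2.05, -0.72 and -1.33 in control replicates 1 to 3 (SD 1.80, n = 3). JRG21, a jasmonate-regulated gene, was at 0.17, 2.15 and -2.33 (SD 2.25, n = 3).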
